A study of Mus musculus with 6 samples.

How the data were processed

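RNA from sorted mouse lung group 2 innate lymphoid cells (ILC2s) was measured in 3 WT and 3 CB2 KO samples. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, BALB/c mice of 6 weeks received 3 intranasal doses of 1 µg recombinant IL-33, and the isolated cells were kept for 24 h with IL-2 and IL-7 at 10 ng/mL each. Libraries were made from 10 ng of RNA and sequenced on an Illumina NextSeq system, per the labels' protocols and the series design text. The labels do not say whether the replicates of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

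The authors deposited an estimated count for each gene and sample, made with Partek's expectation-maximization step, per the file headers and names. The submitters' processing notes list CASAVA 1.8.2, STAR with the version given as 3.5.3, Partek and the mouse build mm10. Estimated counts need not be whole, because a read that fits several genes is shared out between them; between 55.6% and 58.3% of the values of a library lay within 0.01 of a whole number. The strand setting of the counting is not given in the sources used here, so overlapping genes on opposite strands cannot be told apart. The table lists 18478 genes, and the lowest total over the 6 libraries is 10. Start positions and symbols of 17810 of the 17980 genes that match GENCODE release M21 by symbol and chromosome are equal to that annotation, with each deposited stop 1 above its end; ends are given here as GENCODE counts them. The authors also deposited a normalized signal for the same genes: the values equal the estimated count plus 1, divided by a factor per library that sets the 75th percentile to 44.6 in every library.

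Totals per library were 21621008, 20749633 and 17850840 estimated counts for WT replicates 1 to 3, and 19878618, 21103769 and 17141698 for CB2 KO replicates 1 to 3. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.139 to 0.175 CPM, the counts scaled to library size. Such limits, and the intervals of ratios of counts, cover counting error only, since no molecular identifiers are mentioned in the labels. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 32.9), so none was treated as a second copy of another.

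Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr on the 2 groups, glmQLFit with robust=TRUE and legacy=FALSE, glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 14084 genes and removed 4394. The plan lists legacy=TRUE as an alternative and does not spell out legacy=FALSE for this test; a first trial with the package default (legacy=TRUE) gave 13 genes, against 15 here. Standard errors of log2 fold changes were taken as the fold change divided by the root of its F statistic. CPM values use the TMM-scaled library sizes. Positive log2 fold changes mean higher in CB2 KO.

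For gene groups, 41 lists with 1004 entries were written: programs of ILC2s and lymphocytes, markers of other cell types, and technical lists. Of the entries, 863 were found in the table, 26 of them through another symbol. The 32 lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. At the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes the few residual degrees of freedom of these libraries. A call lost there can therefore reflect low power as well as correlation between genes. Camera compares a list with the other genes, whereas fry asks only whether the members of the list changed, so their calls answer different questions.

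These lists, the tests above, the alternatives other than those named below as chosen later, and a rule for the genes named were fixed before the data were examined. The rule takes Cnr2 and genes past the threshold whose groups do not overlap and whose mean CPM is at least 1, up to 12 in each direction. It adds 9 fixed genes (Gata3, Il1rl1, Il5, Il13, Il7r, Il2ra, Nfkb1, Nfkb2 and Mki67) and up to 4 members with the smallest p from each list. The members are printed for the called lists and for 6 further lists that were picked after first values had been seen. Any other gene named was chosen after its values were seen. Some genes that the rule selects are not reported here.

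The workflow was tested on simulated data with the same 14084 genes and library sizes, in which 200 genes were changed. It called 27 of 100 genes changed 2-fold and 70 of 100 changed 4-fold, and 8 unchanged genes. Among genes with a mean CPM of at least 100, all 15 changed 2-fold and all 29 changed 4-fold were called. With 200 changed genes the adjusted threshold is easier to pass than with the few calls of the real data. There an abundant gene with a 2-fold difference can be missed. Myo6, at 295 ± 8.04 CPM in WT and 145 ± 31.1 CPM in CB2 KO, had an adjusted p of 0.086 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With no list changed, 0 lists were called, and with 1 list lowered, 1 was called. The simulated genes were drawn independently of each other. These list counts therefore do not show how often lists are called where genes vary together.

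The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors and filters, other quasi-likelihood settings, unrounded counts, limma on the authors' normalized signal as log2(value + 1) and log2(value + 0.1), the replicate number as a block, other thresholds, and leaving out each library. Alternatives chosen after seeing the data were protein-coding genes only, a mean count of at least 100, removal of chromosome 4, and the list test without the library labelled CB2 KO replicate 1 and with an estimated correlation. Similarity between transcripts was searched with BLAST+ 2.17.0 against GENCODE M21. Other calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Reads and the genome sequence were not used here, so exon-level coverage of Cnr2 and sequence variants were not analysed here.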

Results

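ILC2s are tissue lymphocytes without antigen receptors that make type 2 cytokines such as IL-5 and IL-13. They were sorted from the lungs of WT mice and of mice lacking cannabinoid receptor 2 (CB2), a G protein-coupled receptor of immune cells encoded by Cnr2, after airway exposure to the alarmin IL-33. The series asks how CB2 affects the ILC2 transcriptome, and its only comparison is CB2 KO against WT with 3 libraries each. Totals ran from 17141698 to 21621008 estimated counts per library, and the 10 most abundant genes held 5.12 to 5.45% of them. The library labelled CB2 KO replicate 1 stood apart from the other 5. It lay alone on the first principal component (37.6% of the variance), had the fewest genes with at least 1 count (15021, against 15650 to 16526 elsewhere), and listed 30.3% of genes with a mean count of 10 to 100 at 0, against 13.2 to 23.4% elsewhere.

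Cnr2, the targeted gene (chromosome 4, 135895394 to 135920207, plus strand, mm10), was at 14.2 ± 4.26 CPM in WT and 4.89 ± 3.93 CPM in CB2 KO (mean ± SD, n = 3 each), a mean 65.4% lower. WT replicates 1 to 3 had 200, 356 and 279 counts, or 9.32, 17.4 and 15.8 CPM. The libraries labelled CB2 KO replicates 1, 2 and 3 had 186, 34 and 66 counts, or 9.24, 1.6 and 3.84 CPM, so the library labelled CB2 KO replicate 1 was level with the lowest WT library. The log2 difference of -1.52 (SE 0.56) did not pass the test over all genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.514). An exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 allows. Counts over the whole gene cannot show which part of the transcript was deleted. Without the library labelled CB2 KO replicate 1 the log2 difference for Cnr2 was -2.42, and all directions given here for CB2 KO include that library unless stated.

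Of 14084 tested genes, 6 rose and 9 fell in CB2 KO. Among those that rose was Il9, the gene of the type 2 cytokine IL-9 (chromosome 13, 56479277 to 56482246), from 73.2 ± 10.0 CPM in WT to 309.5 ± 66.0 CPM in CB2 KO (n = 3 each). That was 4.25-fold, with a log2 change of 2.09 (SE 0.20), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.0192. Every CB2 KO library was above every WT library for Il9. Leaving out a library ended the call of Il9 in edgeR's test with Benjamini-Hochberg adjustment, with adjusted p of 0.265, 0.222 and 0.169 without WT replicates 1, 2 and 3, and 0.0827 and 0.174 without CB2 KO replicates 2 and 3. Without the library labelled CB2 KO replicate 1 the adjusted p of Il9 by the same test was 0.0055, its fold remained between 1.95 and 2.26 on the log2 scale in all 6 fits, and limma-voom gave 0.0594.

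Of the 15 genes, 7 lie on chromosome 4, the chromosome of Cnr2. Cep85, which encodes a centrosomal protein, fell 7.46-fold, from 599 ± 37.0 to 80.5 ± 2.13 CPM (log2 change -2.90, SE 0.09). Cap1, which encodes a cyclase-associated actin regulator, rose 6.23-fold, from 137 ± 8.01 to 852 ± 41.7 CPM (log2 change 2.64, SE 0.08). Both had an adjusted p of 1.59e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The histone deacetylase gene Hdac1 fell by 1.03 on the log2 scale (SE 0.12), the microtubule regulator gene Stmn1 by 0.85 (SE 0.09) and Sh3bgrl3 by 0.81 (SE 0.05). Cd52, which encodes a lymphocyte surface glycoprotein, fell by 0.75 (SE 0.07), and Hmgn2, which encodes a nucleosome-binding protein, by 0.70 (SE 0.06). Distances to Cnr2 ranged from 1.4 Mb for Stmn1 to 6.4 Mb for Hdac1, with Cap1 farther away, at 122859047 to 122886056. In the annotation Cap1 overlaps Ppt1, Sh3bgrl3 overlaps Ubxn11 and Cd52 overlaps Crybg2, so counts of these genes are uncertain where the strand was not used. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Hdac1, Stmn1 and Cd52 lost their call without any 1 of the 6 libraries, WT replicates 1 to 3 and CB2 KO replicates 1 to 3 in turn (adjusted p = 0.335, 0.289, 0.169, 0.191, 0.201 and 0.288 for Hdac1; 0.265, 0.222, 0.207, 0.0743, 0.0674 and 0.253 for Stmn1; 0.0781, 0.069, 0.169, 0.0672, 0.118 and 0.173 for Cd52). Hmgn2 lost it by the same test without WT replicates 1, 2 and 3 (0.0781, 0.0767 and 0.0602) and CB2 KO replicates 2 and 3 (0.0674 and 0.0845), and Sh3bgrl3 without WT replicate 2 (0.0551) and CB2 KO replicate 3 (0.0746). On all 6 libraries, Hdac1 also lost its call with upper-quartile factors, library size alone, limma-voom, no filter or legacy=TRUE. Stmn1 also lost it with legacy=TRUE.

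The other 7 called genes are on other chromosomes and are mostly pseudogenes or noncoding. Gm4864 (chromosome 12) rose 8.51-fold, Gm48609 (chromosome 13) 7.54-fold, Gm49980 (chromosome 18) 6.37-fold and Cnbd2 (chromosome 2) 5.69-fold. Gm42031 (chromosome 8) fell 30.7-fold, from 153 ± 4.98 to 4.99 ± 0.66 CPM, Gm10182 (chromosome 9) fell 3.32-fold and Gm43305 (chromosome 14) 2.70-fold. Several are copies of expressed genes, and their counts are uncertain: Gm10182 shares 97.8% of 279 nt with Hmgn2, Gm4864 94.3% of 1470 nt with Hdac1, and Gm48609 94.98% of 239 nt with Rbbp4, which is also on chromosome 4. Transcripts of Gm42031 and Cnbd2 share 90.8% of 607 nt and 92.0% of 591 nt with Cep85. Across the 15 genes the adjusted p ran up to 0.049 (Hdac1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out WT replicates 1, 2 and 3 and CB2 KO replicates 1, 2 and 3 in turn ended the calls of Gm4864, Gm48609, Gm49980 and Cnbd2 by the same test each time (adjusted p = 0.138, 0.17, 0.169, 0.0524, 0.0827 and 0.122 for Gm4864; 0.373, 0.324, 0.352, 0.124, 0.132 and 0.174 for Gm48609; 0.271, 0.223, 0.216, 0.0672, 0.132 and 0.2 for Gm49980; 0.265, 0.223, 0.216, 0.0672, 0.132 and 0.202 for Cnbd2). Gm10182 lost it without WT replicates 1, 2 and 3 (0.0731, 0.0767 and 0.0809) and CB2 KO replicates 2 and 3 (0.0674 and 0.0845), and Gm43305 without WT replicates 1, 2 and 3 (0.077, 0.069 and 0.0602) and CB2 KO replicate 3 (0.0845). On all 6 libraries, Gm48609 also lost its call with limma-voom, legacy=TRUE and the authors' normalized signal. With the replicate block, only Cap1, Cep85 and Gm42031 of the 15 genes kept theirs. Leaving out WT replicate 1, 2 or 3 left 4, 3 and 4 genes past the threshold, and leaving out CB2 KO replicate 1, 2 or 3 left 8, 5 and 3; Cap1, Cep85 and Gm42031 kept their call under all 18 alternatives. DESeq2 called 363 genes on the same counts, 167 higher and 196 lower, including all 15.

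**Figure D1:**
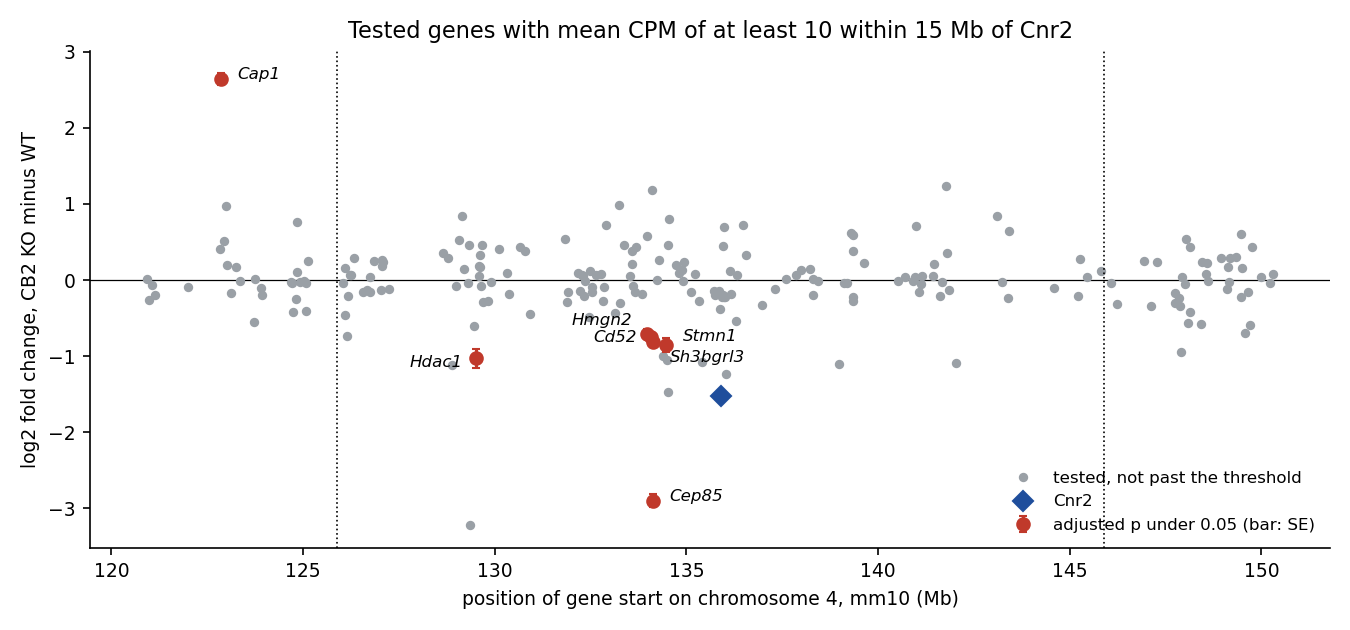
Log2 fold change (CB2 KO minus WT, vertical axis) of tested genes with a mean CPM of at least 10, against the position of their start on chromosome 4 in Mb (mm10, horizontal axis); red points passed the threshold and carry their SE, the blue diamond is Cnr2, and dotted lines lie 10 Mb from it. The called genes within the dotted lines all fell and all have lower coordinates than Cnr2, while Cap1 rose by 2.64 on the log2 scale outside them.

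Of 25 tested ILC2 identity genes, 15 had a negative and 10 a positive log2 fold change, with a median of -0.06. Of the 15 with a mean CPM of at least 100, 12 were at a lower mean in CB2 KO and 3 at a higher one. Their median log2 difference was -0.13. Gata3, the transcription factor that defines ILC2s, was at 1057 ± 55.2 CPM in WT and 964 ± 28.2 CPM in CB2 KO, and the IL-33 receptor gene Il1rl1 at 964 ± 59.3 and 924 ± 23.2 CPM (n = 3 each). Of 25 tested identity genes, 0 passed the threshold over all genes and 2 were lower when adjusted over the list alone: Ly6a, which encodes Sca-1, at 2144 ± 165 against 1578 ± 18.5 CPM, and the neuromedin U receptor gene Nmur1 at 187 ± 11.9 against 117 ± 8.46 CPM. Icos was at 552 ± 58.3 and 431 ± 32.4 CPM, and Klrg1 at 156 ± 13.8 and 114 ± 17.2 CPM. The list as a whole was not called by camera (Benjamini-Hochberg adjustment, adjusted p = 0.11; adjusted p = 0.3 with an estimated correlation), while fry called it lower (adjusted p = 0.0146). The cytokine receptor genes Il7r and Il2ra, which bind the cytokines added in culture, differed by log2 -0.28 (SE 0.13) and -0.21 (SE 0.07) and did not pass the test.

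Of 22 tested effector cytokines and secreted factors, Il9 was the 1 gene past the threshold over all genes. Adjusted over the list alone, 3 were higher and 2 lower. Il9 was joined by Csf2, the GM-CSF gene, at 541 ± 6.14 against 831 ± 99.4 CPM, and by Il5, at 7343 ± 469.6 against 9021 ± 1070.0 CPM. The lower genes were Lif, at 37.3 ± 15.1 against 9.32 ± 5.88 CPM, and Il2, at 2.41 ± 1.19 against 0.54 ± 0.14 CPM. Il13 was at 75.98 ± 7.14 and 89.97 ± 15.7 CPM, a log2 difference of 0.25 (SE 0.17) that did not pass. The list was not called (camera with Benjamini-Hochberg adjustment, adjusted p = 0.13), with 16 members positive and 6 negative, but was called higher without the library labelled CB2 KO replicate 1 (adjusted p = 0.0433 by the same test, but adjusted p = 0.39 with an estimated correlation). Fry with Benjamini-Hochberg adjustment called the effector cytokine list on all 6 libraries (adjusted p = 0.00572, direction higher). Its mean shift from WT was -0.22, 0.18 and 0.07 in CB2 KO libraries 1 to 3. The 14 tested endocannabinoid receptors and enzymes, with 0 past the threshold over all genes and 0 adjusted over the list alone, were not called either (adjusted p = 0.657 by the same test). Pparg was at 260.0 ± 19.5 and 306 ± 8.68 CPM, Abhd6 at 15.8 ± 4.87 and 22.2 ± 1.73 CPM, and the anandamide hydrolase gene Faah at 72.1 ± 12.8 and 90.7 ± 17.9 CPM.

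**Figure D2:**
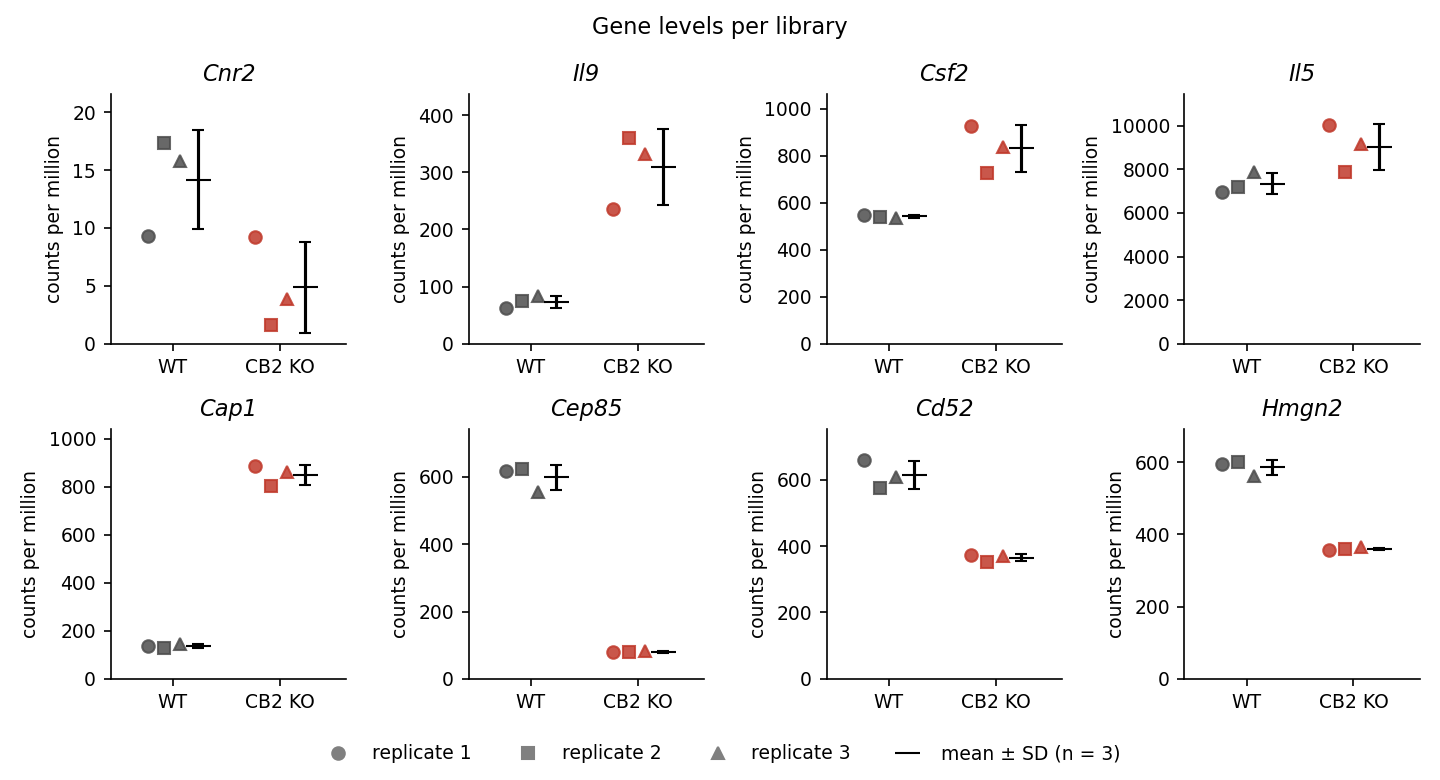
CPM (vertical axis, starting at 0) of 8 genes in each WT (grey) and CB2 KO (red) library; symbols mark the replicate number, and the black mark and bar give the mean ± SD of 3 libraries. Il9, Cap1, Cep85, Cd52 and Hmgn2 passed the test over all genes, while Cnr2, Csf2 and Il5 did not, and Cnr2 in the library labelled CB2 KO replicate 1 (9.24 CPM) is level with WT replicate 1 (9.32 CPM).

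Genes of cell division were lower in CB2 KO as groups at the preset correlation of camera. The call was lost when camera estimated the correlation (adjusted p = 0.0927 for G2 and M phase and 0.293 for S phase, Benjamini-Hochberg adjustment). The estimates were 0.011 and 0.0153, near the preset 0.01, so stronger correlation between genes does not by itself account for the loss. That test also rests on far fewer degrees of freedom, so losing the call there does not show that the lists were unchanged. Of 53 tested genes of the G2 and M phase list, 47 had a negative log2 fold change, with a median of -0.29. None passed over all genes (0 of 53) and 8 were lower when adjusted over the list alone. Among them were the chromatin protein gene Hmgb2 (697 ± 21.3 against 554 ± 9.16 CPM), the mitotic ubiquitin-conjugating enzyme gene Ube2c (357 ± 32.8 against 253.5 ± 8.36 CPM), the cytokinesis gene Anln (78.1 ± 6.19 against 46.3 ± 6.09 CPM) and cyclin B1, Ccnb1 (264 ± 18.7 against 205 ± 12.2 CPM). Mki67, a proliferation marker, was at 340 ± 16.1 and 281 ± 32.6 CPM. Camera with Benjamini-Hochberg adjustment called the list lower, with an adjusted p of 1.34e-09, but adjusted p = 0.0927 with an estimated correlation. The S phase list was also called lower (adjusted p = 0.00212 by the same test, but adjusted p = 0.293 with an estimated correlation), with 32 of 43 tested genes negative and 0 passing over all genes or adjusted over the list alone. Slbp was at 504 ± 10.1 and 400.0 ± 28.5 CPM, and the ribonucleotide reductase gene Rrm2 at 1474 ± 35.3 and 1250.0 ± 75.7 CPM. E2f8 was at 64.4 ± 3.78 and 39.5 ± 8.07 CPM. The mean shift of the G2 and M phase genes from WT was -0.37, -0.28 and -0.25 in CB2 KO libraries 1 to 3. Without the library labelled CB2 KO replicate 1, camera with Benjamini-Hochberg adjustment gave an adjusted p of 2.74e-08 for this list and 0.00936 for S phase, but adjusted p = 0.281 and 0.39 with an estimated correlation.

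Cholesterol and fatty acid synthesis genes were lower as a group at the preset correlation of camera, but not with an estimated correlation. Of 29 tested, 28 had a negative log2 fold change (median -0.36), and 0 passed over all genes or adjusted over the list alone. The squalene synthase gene Fdft1 was at 67.7 ± 4.37 against 42.0 ± 3.08 CPM, the fatty acid synthase gene Fasn at 284 ± 28.5 against 222 ± 25.2, and Fdps at 157 ± 17.7 against 121 ± 7.16. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 2.12e-07, but adjusted p = 0.3 with an estimated correlation. The mean shift of this list was -0.85 in the library labelled CB2 KO replicate 1 and -0.19 and -0.30 in replicates 2 and 3. Without that library the adjusted p by camera was 0.00028, but adjusted p = 0.281 with an estimated correlation.

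Targets restrained by AKT through FOXO factors and genes of the NF-kappaB pathway were called higher as groups only at the preset correlation of camera, and neither call held with an estimated correlation, by fry or without the library labelled CB2 KO replicate 1. Of 17 tested AKT-FOXO targets, 13 had a positive log2 fold change, with 0 past the threshold over all genes and 1, the chemokine receptor gene Ccr7, higher when adjusted over the list alone (31.2 ± 2.80 against 61.6 ± 12.4 CPM). Gabarapl1 was at 24.5 ± 5.32 and 42.3 ± 8.46 CPM, Sesn1 at 34.0 ± 4.88 and 54.7 ± 11.4 CPM, and Tsc22d3 at 63.2 ± 4.88 and 84.2 ± 13.9 CPM. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.0147, but adjusted p = 0.3 with an estimated correlation; it was 0.101 without the library labelled CB2 KO replicate 1 and 0.0695 without WT replicate 2. Of 32 tested NF-kappaB genes, 24 were positive, with 0 past the threshold over all genes. The 1 gene that passed when adjusted over the list alone, Nfkb1, which encodes the p105 precursor, was lower (426 ± 19.5 against 330.2 ± 17.7 CPM). Nfkb2 was at 115 ± 20.1 and 143 ± 26.7 CPM, the inhibitor gene Nfkbia at 93.0 ± 5.50 and 131 ± 17.3 CPM, Icam1 at 78.2 ± 9.53 and 111 ± 7.73 CPM, and Ikbkg at 43.7 ± 11.8 and 72.1 ± 13.6 CPM. Camera with Benjamini-Hochberg adjustment gave the NF-kappaB list an adjusted p of 0.0176, but adjusted p = 0.3 with an estimated correlation. That call was lost without the library labelled CB2 KO replicate 1 (adjusted p = 0.0732 by camera), without CB2 KO replicate 3 (0.114) and without WT replicate 1 (0.111).

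**Figure D3:**
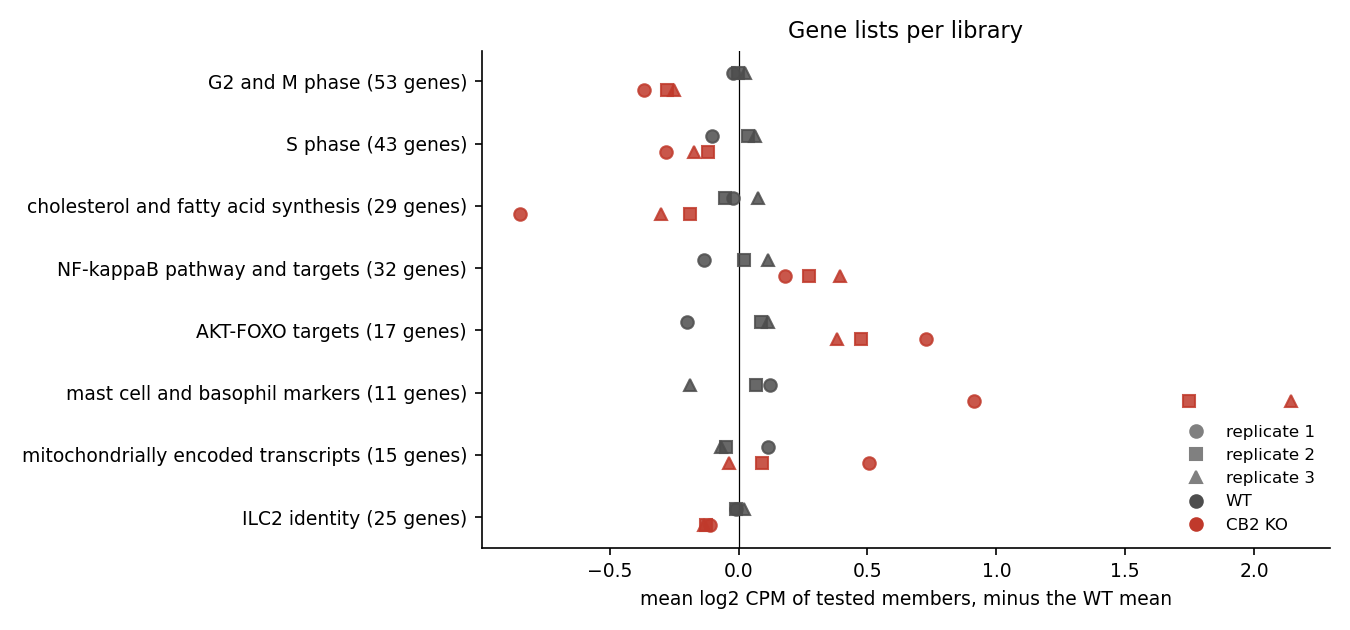
Mean log2 CPM of the tested members of 8 gene lists, relative to the WT mean (horizontal axis), in each WT (grey) and CB2 KO (red) library; symbols mark the replicate number. The G2 and M phase genes are lower in all 3 CB2 KO libraries (-0.37, -0.28 and -0.25), and the cholesterol and mitochondrial lists lie farthest from WT in the library labelled CB2 KO replicate 1 (-0.85 and 0.50).

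Markers of other cell types were measured in the same libraries. Of 11 tested mast cell and basophil markers, 9 were positive, with 0 past the threshold over all genes and 1 higher when adjusted over the list alone. This was the tryptase gene Tpsb2, at 2.29 ± 0.94 against 23.3 ± 8.41 CPM; Tpsab1 was at 0.61 ± 1.05 and 9.23 ± 7.77 CPM and Mcpt8 at 2.96 ± 0.23 and 6.37 ± 1.97 CPM. Kit, which mast cells and some ILC2s express, went the other way, at 198 ± 16.9 and 134.5 ± 41.6 CPM. Camera with Benjamini-Hochberg adjustment called the list higher with an adjusted p of 0.0018, but adjusted p = 0.27 with an estimated correlation. That estimate was -0.04, below the preset 0.01, so stronger correlation between genes does not account for the loss. The fewer degrees of freedom of that test apply here too. The call was also lost among genes with a mean count of at least 100 (adjusted p = 0.173 by camera). Of 7 tested macrophage and monocyte markers, 0 passed over all genes and, adjusted over the list alone, 2 were higher and 1 lower. The lysozyme gene Lyz2 was at 1.64 ± 0.79 and 17.3 ± 5.98 CPM, Chil3 at 18.9 ± 25.1 and 128 ± 18.4 CPM, Csf1r at 0.49 ± 0.84 and 3.98 ± 3.48 CPM, and Ccr2, which ILC2s also express, at 1070.0 ± 40.6 and 718 ± 61.4 CPM. Of 12 tested T cell markers, 0 passed over all genes and 1 was lower when adjusted over the list alone, the T cell receptor gamma constant gene Trgc1 at 215 ± 15.2 and 130 ± 14.9 CPM. Cd3g was at 13.96 ± 3.93 and 26.1 ± 2.53 CPM, Cd3e at 0.28 ± 0.44 and 2.03 ± 1.40 CPM, and Trbc1 at 44.3 ± 0.71 and 59.8 ± 14.5 CPM. The macrophage and T cell lists were not called (camera with Benjamini-Hochberg adjustment, adjusted p = 0.251 and 0.657), nor were dendritic cell (0.114) and lung epithelial markers (0.999).

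The mitochondrially encoded transcripts were called higher (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0326), but adjusted p = 0.669 with an estimated correlation. Of 15 tested, 14 were positive and 0 passed over all genes or adjusted over the list alone. mt-Co1 was at 927.5 ± 39.3 and 1165 ± 187 CPM, mt-Cytb at 1218 ± 29.5 and 1451 ± 197 CPM, mt-Nd1 at 696 ± 39.3 and 825 ± 139 CPM, and mt-Nd2 at 133 ± 4.94 and 175 ± 47.5 CPM. The list shifted by 0.50 in the library labelled CB2 KO replicate 1 and by 0.09 and -0.04 in replicates 2 and 3, and mitochondrial reads were 0.96% of that library against 0.65 to 0.76% elsewhere. The adjusted p by camera was 0.828 without that library, 0.185 without WT replicate 2 and 0.179 without WT replicate 3.

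The other 25 tested lists were not called by camera, with adjusted p from 0.0769 to 0.999 with Benjamini-Hochberg adjustment. The lowest was that of the technical list of heat shock and dissociation stress (0.0769). Programs not called by camera included apoptosis and survival (0.114), interferon response (0.13), glycolysis (0.162), oxidative phosphorylation (0.767), unfolded protein response (0.915), and IL-2 and IL-7 STAT5 targets (0.641). They also included G protein and cyclic AMP signalling (0.69), the pathway class of CB2, where 0 of 33 tested genes passed over all genes or adjusted over the list alone, and MAP kinase and AP-1 immediate early genes (0.376). Markers of NK cells, ILC3s, B cells, neutrophils, eosinophils, endothelium, fibroblasts and erythroid cells and the sex-linked transcripts had too few tested members (1 to 4 each). Without the library labelled CB2 KO replicate 1, camera called 5 lists, against 7 with it: G2 and M phase, S phase, cholesterol and fatty acid synthesis, mast cell and basophil markers, and effector cytokines. With an estimated correlation 0 lists were called by camera, with or without that library. With so few residual degrees of freedom that test has little power, so the 0 does not show that no list changed. Fry with Benjamini-Hochberg adjustment called 6 lists. Of the 7 called by camera it called 2, G2 and M phase (adjusted p = 0.00572, lower) and mast cell and basophil markers (0.0146, higher). It also called effector cytokines (0.00572, higher) and apoptosis and survival genes (0.0328, higher), and ILC2 identity genes (0.0146) and the neighbours of Cnr2 (0.00572) lower. The mean shift of the apoptosis and survival list from WT was -0.38, 0.06 and 0.09 in CB2 KO libraries 1 to 3. Its mean log2 CPM difference was -0.08, against the direction of the call.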

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

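The protein-coding, mean count and chromosome 4 settings, and the list test without the library labelled CB2 KO replicate 1 at an estimated correlation, were chosen after seeing the data. Against 15 called genes (6 higher, 9 lower), DESeq2 called 363 (167 and 196), protein-coding genes alone 28 (13 and 15), and a mean count of at least 100 gave 35 (16 and 19). Removal of chromosome 4 left 5 (2 and 3), so some of the genes called higher on other chromosomes lost their call as well. An adjusted p under 0.1 gave 38 (17 and 21), one under 0.01 gave 7 (1 and 6), and a 2-fold minimum left 5 lower genes. Leaving out 1 library gave 3 to 8 genes, 1 to 2 of them higher and 2 to 6 lower, in fits with fewer samples. The legacy=TRUE setting gave 13 genes, limma-voom 16 (4 higher, 12 lower; 12 shared with the 15), and the authors' signal 21. For the counts other than those with fewer samples or genes, the cause was not tested.

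The replicate numbers gave no clear sign of pairing. Same-numbered libraries correlated at 0.07, 0.03 and 0.02 in their deviations from the group means. Of 6 libraries, 3 correlated best with their own number. Deviations from the means of so few libraries are a weak check. No label says whether the numbers mark a shared litter or day, so pairing stays unknown. The replicate block left 3 genes (1 higher, 2 lower) and 7 lists. Of the 70 genes followed, which include members of the lists picked later, 0 reversed: 1147 gene and setting pairs kept their side of the threshold, 86 lost it and 27 gained it. Many of these genes were chosen for a small p in these same libraries, so reversals were unlikely from the start. The log2 difference of Cnr2 lay between -2.42 and -1.06. The 7 called lists became 0 with an estimated correlation, also 0 without the library labelled CB2 KO replicate 1, and 5 to 8 when 1 library was left out. The test with an estimated correlation has little power with so few libraries. Scaling moved the median of all genes by at most 0.02 (log2). The median biological coefficient of variation was 93.2% below a mean count of 100 and 15.3% above 1000, and 0 of 3587 genes below 100 were called.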

Other observations

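Genes just outside the threshold included surface receptors, a lipid droplet gene and an autophagy adaptor; they were picked after their values were seen. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 23 genes had an adjusted p between 0.05 and 0.1, 11 of them higher and 12 lower in CB2 KO. The IL-1 decoy receptor gene Il1r2 was at 217 ± 10.6 CPM in WT and 389 ± 48.8 CPM in CB2 KO (n = 3 each), a log2 difference of 0.84. Sqstm1, which encodes the autophagy adaptor p62, was at 464 ± 25.0 and 737 ± 67.2 CPM, and Plin2, which coats lipid droplets, at 548 ± 48.9 and 801 ± 30.7 CPM. The unconventional myosin gene Myo6 was at 295 ± 8.04 and 145 ± 31.1 CPM, and the tubulin gene Tuba1b at 2082 ± 62.2 and 1674 ± 46.5 CPM.

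Among the fixed lists, the apoptosis and survival list held 2 genes that were higher when adjusted over the list alone and 0 over all genes, both targets of p53: Cdkn1a at 473 ± 19.5 against 600.4 ± 12.7 CPM and Mdm2 at 172 ± 14.6 against 234.5 ± 4.49 CPM. The chemokine receptor and adhesion list held 2 higher and 2 lower genes adjusted over the list alone and 0 over all genes; Ccr4 was at 57.9 ± 10.3 against 93.8 ± 13.6 CPM, and Itgb7 at 719 ± 40.7 against 531 ± 81.8 CPM. In the class II antigen presentation list 1 gene was higher adjusted over the list alone and 0 over all genes, the invariant chain gene Cd74 at 41.3 ± 8.79 against 79.5 ± 7.75 CPM. Of 18 tested genes known to vary between inbred strains, 1 was higher and 1 lower adjusted over the list alone, and 0 passed over all genes: Wdfy1 was at 7.06 ± 3.52 against 50.8 ± 9.62 CPM and Ly6e at 1801 ± 72.9 against 1421 ± 23.3 CPM. In 7 of the 32 tested lists, 0 of them called by camera, the median, the mean and the test differed in sign. Apoptosis and survival, which fry called higher, was among them.

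The tests on copies of genes were chosen only after the result was seen, while the window test and its 10 Mb were planned, with the p under 0.05 by which it is read written later. The called genes lay near Cnr2: within 10 Mb of it, 6 of 226 tested genes were called, against 9 of 13857 elsewhere (Fisher's exact test, two-sided p = 7.09e-08, Cnr2 left out), and all 6 fell and lie below Cnr2, with 0 of 84 tested genes above it called. DNA of another strain around the targeted allele would give such a cluster and stays open, as do direct effects of the deletion on its neighbours, which were not tested; the window test cannot separate these, and sequence variants were not analysed here. Of the 4 searched genes away from chromosome 4 that rose, 3 resembled a transcript from the window whose own level was lower. These were Cnbd2, Gm4864 and Gm48609 (at least 90% identity over at least 200 nt). Among 350 matched uncalled genes, 4 had a match that moved the opposite way (Fisher's exact test, two-sided p = 1.89e-05). For Gm48609 the match is Rbbp4, lower by only log2 -0.04. Cnbd2 is a protein-coding gene that shares a stretch of 591 nt with Cep85, which does not make it a copy. Reads were not followed, so their movement to similar genes stays possible for these rises and was not shown. Il9 had no match in the window. Gm42031 and Gm10182, which fell together with their matches Cep85 and Hmgn2, were not part of that test. Whether their reads went to other copies was not tested. For Hmgn2, 3 similar genes were higher in sum (Gm10282, Gm6594 and Gm7125, 167.6 ± 7.53 against 273.4 ± 12.4 CPM, with Gm6594 at 0.03 and 18.2 CPM). This rise equals 47.0% of the fall of Hmgn2, but Gm10182 fell as well, from 125 CPM in WT to 37.6 CPM in CB2 KO. The sum of Hmgn2 and 4 similar genes was lower, at log2 -0.39 (SE 0.03). Reads moving among these genes thus do not account for the whole fall, while movement to copies not counted stays open.

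The comparison with WT at called genes was chosen only after the result was seen. In the library labelled CB2 KO replicate 1, Cnr2 stood 57.0% of the way from the mean of the other CB2 KO libraries to the WT mean. A WT library under that label, or WT RNA mixed into it, is argued against by the 8 genes called without that library, which stood a median of -1.2% of the way (range -8.1 to 40.8%, the highest being Il9). Scatter of low-count genes stays open: the deviation of Cnr2 in that library from the other CB2 KO libraries exceeded those of 81.0% of 500 genes of similar mean CPM, short of the 95% set beforehand. A transcript left by the targeted allele, at a different level in each library, was not tested, since counts cover the whole gene.

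Leaving out each library was planned, but its use as a test of this pattern, its fit with an estimated correlation, and the test of marker sums with its limit were chosen only after the result was seen. The library labelled CB2 KO replicate 1 alone does not account for the lower G2 and M phase list at the preset correlation, since camera with Benjamini-Hochberg adjustment gave an adjusted p of 2.74e-08 without it, but adjusted p = 0.281 with an estimated correlation (0.0927 with the library). To lower the list by its median of -0.29, other cells would have to supply 18.4% of the RNA, and the values argue against this for the 13 cell types with a marker list: the summed markers under 100 CPM in WT differed most for macrophages and monocytes (63.3 ± 27.5 and 191.5 ± 19.0 CPM), at most 0.0908% of such added RNA, against 1.125% of WT counts in the ILC2 identity list. Cells without a marker list stay open. The marker sums leave out genes at 100 CPM or more in WT and rest on as few as 3 genes. The sum of the identity list keeps its abundant genes, so these shares are not measured alike. The argument is therefore weaker for cell types with few markers. The 18.4% also assumes that other cells hold no RNA of the G2 and M phase list. The 15 identity genes with a mean CPM of at least 100 had a median log2 difference of -0.13. Its 95% bootstrap interval, -0.44 to -0.04, includes the median of the list. That interval resamples the 15 genes and not the libraries, so it leaves out the error between samples. Of these genes, 7 lay above the median of the list by more than 2 SE and 2 below it. A slower cell cycle in CB2 KO ILC2s also stays open, as an untested biological explanation.

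These counts over splits were chosen only after the result was seen. With 3 libraries against 3 there are 10 splits of the samples, too few for a share under 0.05. For the count of genes, 1 of the 10 splits, the real one, gave as many as 15, and the highest of the others gave 0. For the count of lists, 1 of the 10 gave as many as 7, and the highest of the others gave 4.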
